A study of Homo sapiens with 6 samples.

How the data were processed

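Total RNA was extracted with Trizol, and biotin-labelled cRNA was prepared by the Affymetrix protocol, per the labels' protocols. The deposited table holds log2 expression values, 1 per probe set and array. RMA (robust multi-array averaging, which corrects background, quantile-normalizes arrays together and summarises probes) is named per the submitters' processing notes; its version, the probe set definitions and the arrays normalized together are not given in the sources used here. RMA makes the distributions of the arrays alike, so that a change of most genes in one direction would be removed, and it shrinks changes of dim probe sets. The deposited log2 values run from 2.08 to 14.1 and come with no detection call, so no probe set could be called absent. All 6 columns were used.

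Probe sets were named by the RefSeq accession in their identifier, matched without version to the RefSeq gene table of GRCh38: 1043 of 1259 matched 1 symbol each and none matched several. The other 216, of which 26 carry a RefSeq accession, kept their identifiers and stayed in the tests. No identifier marks a control probe set. No coordinates are printed because the build behind the probe sets is not given in the sources used here. For a gene with several probe sets, the one with the highest mean over the 6 arrays was used.

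The 3 F3 arrays were compared with the 3 C2 arrays in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05; every p given for a single gene is from this fit unless stated. Log2 changes are F3 minus C2, and intervals are at 95%. The labels call F3 a population in one place and a clonal population in another, and do not say whether the 3 arrays of a population came from separate cultures, so p-values measure the spread between these samples, which may be technical. No pair of arrays shared more than 0.48% identical values.

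The replicate numbers are shared between the populations, and arrays of the same number also share a label suffix. The deviations of same-numbered arrays from their population means correlated across probe sets with r = 0.52, 0.18 and 0.26 for numbers 1, 2 and 3. Each of the 6 arrays correlated best with its own number, so the numbers were taken to pair the arrays. The mean r was 0.32 for this pairing and 0.23 for the best other one, and C2 replicate 2 had r = 0.15 with F3 replicate 3. With only 6 possible pairings, this is weak evidence, above all for numbers 2 and 3. The fit without a block, as planned, is the main one, so its SEs, intervals and p-values leave the pairing out. Blocked values are given where they change a call. The block lowered the SE of some genes, such as ST6GAL1 (0.12 to 0.058) and HES1 (0.13 to 0.068), without a call (blocked limma adjusted p = 0.47 each). It raised that of others, such as GDF15 (0.113 to 0.118). Ranges over single arrays left out also carry the difference between pairs, since each drops 1 member of a pair.

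Gene lists (21, on glycan synthesis, glycan-binding proteins, u-PAR, signalling and markers of other cell types) were fixed before the data were examined, and the 19 with at least 5 measured genes were tested with camera (preset correlation 0.01), adjusted over the lists. A list of integrins and cadherins was not analysed here. The genes named were chosen by a rule fixed at the same time: the 12 largest changes in each direction past the threshold with no overlap of arrays or, with fewer than 5 genes past it, the 5 smallest p in that direction; in each list up to 4 genes with the smallest p; and all branching GlcNAc-transferases. PLAUR was also to be named and was not analysed here. Some genes that the rule names are not reported here. Alternatives fixed beforehand were the replicate block, median centring, repeated quantile normalization, a filter on dim probe sets, an intensity trend with robust eBayes, array weights, leaving out each array, other thresholds, an ordinary two-sample test, genes in place of probe sets, other list tests and the mean of a gene's probe sets. Leaving out probe sets ending in _x_at and leaving out both arrays of number 2 were added after the data were seen.

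The limma script was tested on simulated data for this comparison (1259 probe sets, 50 simulations, variances drawn from the fitted prior). With 200 changed probe sets it recovered 96.0% of 1.4-fold and 99.7% of 2-fold changes, with 4.6% of calls false. With 10 changed probe sets it recovered 75.6% and 97.6%, with 6.3% of calls false. The simulated arrays carried no pair effect, so these shares do not cover the pairing of the arrays. In 200 simulations on 927 genes with independent errors, camera gave a p under 0.05 for 3% of unchanged lists of 20 genes and for 100% of lists shifted by 0.1 on the log2 scale. Genes of the real lists were correlated, with an estimate of up to 0.37 (GPI anchor synthesis, 9 genes). The 3% and 100% therefore do not cover correlated or shorter lists.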

Results

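Gene expression was measured in 2 populations of RKO, an established human colon carcinoma cell line. RKO C2 is a clonal population. RKO C2 F3 was obtained from it by cell sorting for low surface u-PAR, the urokinase plasminogen activator receptor. The comparison asked which glycosylation enzyme F3 lacks, in cells where u-PAR does not mature fully. u-PAR is a heavily N-glycosylated protein held in the membrane by a glycosylphosphatidylinositol (GPI) anchor. Each population was represented by 3 arrays, numbered 1 to 3 in both. The table held log2 expression values for 1259 probe sets, of which 1043 were named and stood for 927 genes, among them glycosyltransferases, other glycan enzymes, lectins, glycoproteins, cytokines, growth factors and a set of housekeeping genes. Median log2 expression lay between 5.48 and 5.51 on the 6 arrays, and any pair of arrays correlated across probe sets with r from 0.9981 to 0.9992. The median within-group SD was 0.083 on the log2 scale, and the number of arrays limits the precision. The gene encoding u-PAR itself, PLAUR, was not analysed here.

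Limma called 1 of 1259 probe sets different between F3 and C2. PIGB, which encodes the mannosyltransferase that adds the third mannose of the GPI anchor core, fell from a log2 expression of 7.36 ± 0.09 (SD, n = 3) in C2 to 6.49 ± 0.18 (SD, n = 3) in F3. This is a log2 change of -0.87 (SE 0.09, 95% interval -1.08 to -0.66), or 1.82-fold lower, with a limma adjusted p of 0.013. PIGB was lower in F3 in each of the 3 pairs of same-numbered arrays, with differences of -0.82, -1.12 and -0.66. It was also the largest change among the 1259 probe sets, against a median absolute change of 0.047 and a 95th percentile of 0.17. No gene rose past the threshold. Of the 68 probe sets with an unadjusted limma p under 0.05, a total set against chance below, 24 were higher. With the replicate number as a block, the count was 2 probe sets in place of 1. These were PIGB (adjusted p = 0.032) and S100A10, which encodes the p11 partner of annexin A2.

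The PIGB call was lost without C2 replicate 2 (limma adjusted p = 0.057), C2 replicate 3 (0.15), F3 replicate 1 (0.097) or both arrays of number 2 (0.080), and in an ordinary two-sample test, whose smallest adjusted p over all probe sets was 0.86 (limma stabilises the variance of each probe set). Over 14 alternatives in limma its adjusted p ran from 0.0045 to 0.15. The table held a single PIGB probe set, and the RefSeq annotation of GRCh38 places CCPG1 over part of the PIGB locus, and whether these probes also bind CCPG1 transcripts was not determined.

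**Figure D1:**
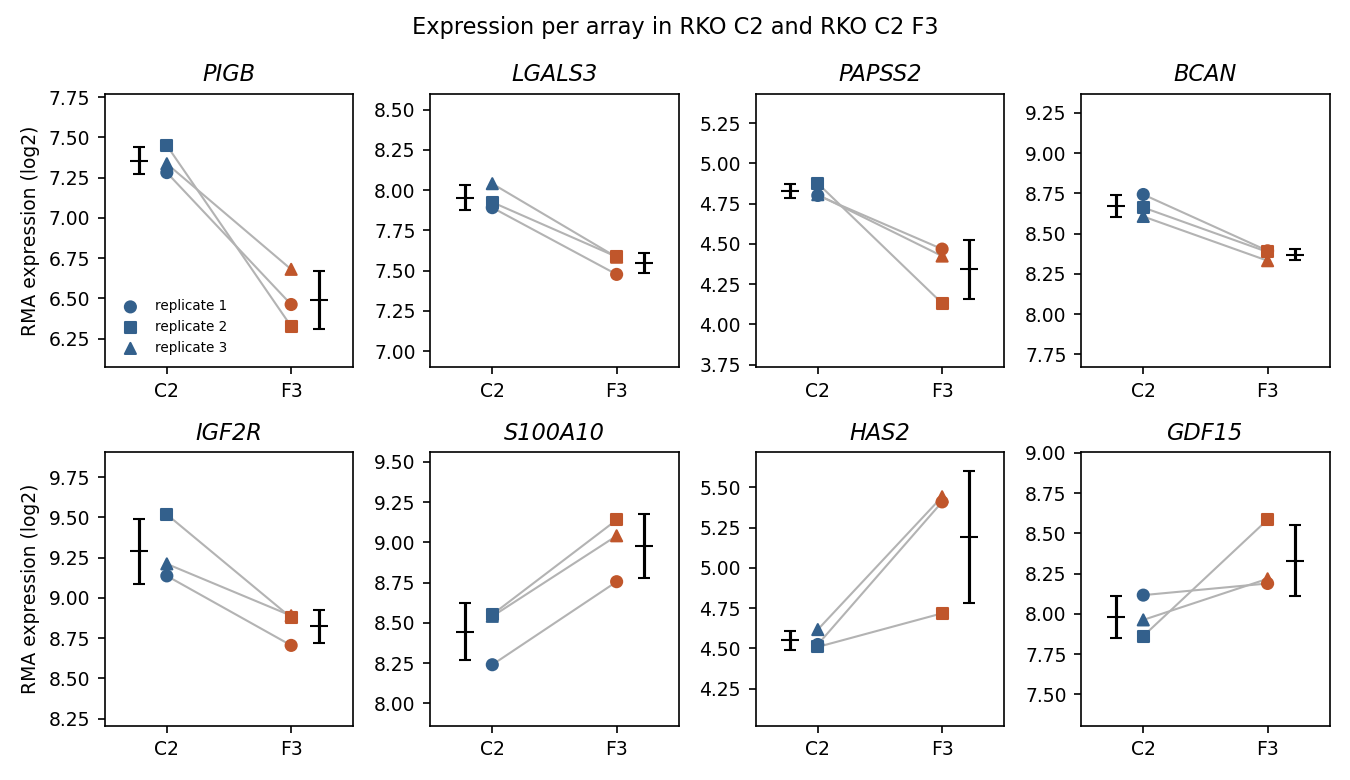
RMA expression on a log2 scale for each array of RKO C2 (blue) and RKO C2 F3 (orange) for 8 genes, with grey lines joining arrays of the same replicate number and black bars giving the mean and SD of 3 arrays. All panels span the same log2 range. The 3 F3 arrays lie wholly below or above the 3 C2 arrays for all 8 genes, which are among those with the smallest p in their direction. HAS2 in F3 replicate 2 (4.72) lies just above the highest C2 array (4.62) and far from the other 2 F3 arrays (5.41 and 5.44).

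Beyond PIGB, the genes with the smallest p did not pass the threshold over all probe sets. LGALS3, encoding the galactoside-binding lectin galectin-3, came nearest, with a log2 change of -0.40 (SE 0.06, adjusted p = 0.095; 0.066 with the replicate block). PAPSS2, which makes the sulfate donor PAPS, had one of -0.49 (SE 0.09, adjusted p = 0.19). IGF2R, the mannose-6-phosphate receptor, had a log2 change of -0.46 (SE 0.10, adjusted p = 0.36). BCAN, encoding the proteoglycan brevican, had one of -0.30 (SE 0.06, adjusted p = 0.19), but its other probe set, at a lower level, was at 0.09. Among the positive changes, S100A10 went from 8.44 ± 0.18 to 8.98 ± 0.20 (SD, n = 3 each), a log2 change of 0.53 with an adjusted p of 0.36. Its 3 paired differences were 0.52, 0.59 and 0.50, and the blocked limma fit gave an adjusted p of 0.031. HAS2, a hyaluronan synthase, had a log2 change of 0.64 (SE 0.17, adjusted p = 0.73), and without F3 replicate 2 the change was 0.88 with an adjusted p of 0.0038, while leaving out each other array in turn gave adjusted p-values up to 0.89. GDF15, a stress-induced cytokine, had a log2 change of 0.35 (adjusted p = 0.84; 0.22 to 0.42 with 1 array left out in turn), CD72 one of 0.23 (0.73) and KLRC3 one of 0.17 (0.84). CD72 and KLRC3 had low log2 levels in C2, 3.64 and 3.34, and the other KLRC3 probe sets were at 0.08, -0.01 and -0.05.

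In total 68 probe sets had an unadjusted limma p under 0.05, 24 of them higher and 44 lower in F3. Chance gives about 63 at this threshold for arrays that are not paired. These arrays were taken to be paired, so 63 is not a sure yardstick for the fit without a block. Other splits of the arrays, 3 against 3, that part every pair gave 16, 25 and 32. Without F3 replicate 2 the observed number was 43. With the replicate block, which allows for the pairing, the number was 101 against about 63 by chance, with 32 higher and 69 lower. Whether 101 is more than chance gives was not tested. The 3 arrays of one population lay entirely above the 3 of the other for 130 probe sets, or 10.3%, where chance gives 10% for arrays that are not paired. The median change over all probe sets was -0.0064. The plot of change against p-value shows the distance of PIGB from the remaining probe sets.

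**Figure D2:**
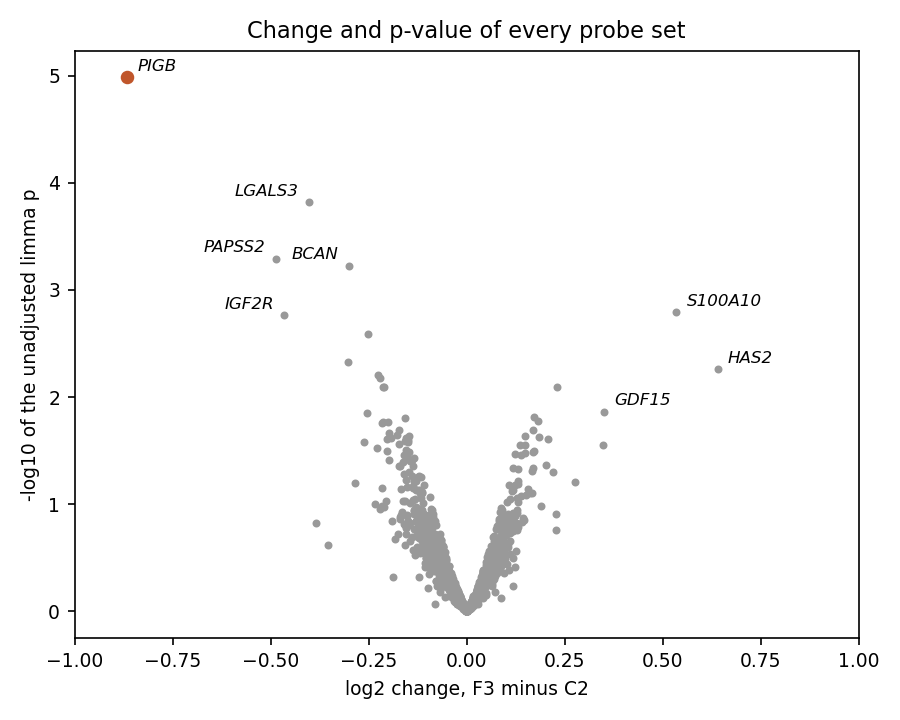
Log2 change (F3 minus C2) against -log10 of the unadjusted limma p for 1259 probe sets, with the probe set past an adjusted p of 0.05 in orange. PIGB, at -0.87, stands apart from the other labelled genes.

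Of 9 measured genes of GPI anchor synthesis, out of 30 on the list, PIGB fell, 0 rose and 8 did not pass. Adjusted over the list alone the count was again 1. The other members ranged from -0.15 for PIGH (95% interval -0.36 to 0.06), a subunit of the first enzyme of the pathway, to 0.07 for PIGQ, with PIGA at -0.12, the dolichol-phosphate-mannose synthase genes DPM1 at 0.0014 and DPM3 at -0.087, and PIGM, which adds the first mannose, at -0.073. Single arrays left out moved PIGH between -0.24 and -0.06, PIGA between -0.16 and -0.08 and DPM3 between -0.12 and -0.04. The list had a camera p of 0.019, and its adjusted p over 19 lists was 0.34; with an estimated correlation the adjusted p was 0.91, and without PIGB it was 0.60 with the preset correlation. Leaving out C2 replicate 1 or F3 replicate 3 brought the list's adjusted p to 0.044 and 0.018, within a range of 0.018 to 0.68 over single arrays left out.

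None of the lists of N-glycan synthesis had a member past the threshold, over all probe sets or adjusted over the list alone. The dolichol-linked precursor and oligosaccharyltransferase list (20 of its 34 genes measured, 15 with a negative change) had a median log2 change of -0.037 and a camera adjusted p of 0.35. ALG9, an ER mannosyltransferase, had the smallest p in it, with a change of -0.25 (SE 0.06, limma adjusted p = 0.46). Next came ALG10 at -0.13, ALG14 at -0.12 and DPM3. With 1 array left out in turn ALG10 ran from -0.19 to -0.04 and ALG14 from -0.21 to -0.05. The trimming and ER quality control list (8 of its 27 genes measured, 6 negative) had a median of -0.037 and a camera adjusted p of 0.34. Its leading members were UGGT2, a homologue of the folding sensor that reglucosylates glycoproteins, at -0.22 (SE 0.06), the lectin chaperone CANX at -0.15, MAN2A2 at -0.17 and MAN1A2 at -0.056. With 1 array left out in turn MAN2A2 ran from -0.22 to -0.08 and MAN1A2 from -0.12 to -0.02.

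None of the 7 measured N-glycan branching GlcNAc-transferases passed in limma, at an unadjusted p under 0.05 either. Their log2 changes lay between -0.095 and 0.12, with the smallest limma adjusted p at 0.97 and an camera adjusted p of 0.60. MGAT1, which starts complex-type N-glycans, was at -0.020 (95% interval -0.22 to 0.18), and MGAT2 at -0.0044 (-0.22 to 0.22). Both were positive after quantile normalization and with some arrays left out, and MGAT2 also after median centring. MGAT3 was at -0.065 (-0.18 to 0.05), MGAT4A at -0.095 (-0.37 to 0.18), MGAT4B at 0.072 (-0.06 to 0.20), MGAT5 at 0.050 (-0.09 to 0.19) and MGAT5B at 0.12 (-0.06 to 0.31). Over single arrays left out MGAT4A ran from -0.23 to -0.00051, MGAT4B from 0.05 to 0.11, MGAT5 from 0.01 to 0.08 and MGAT5B from 0.06 to 0.19. In the fixed list labelled galactosylation and poly-N-acetyllactosamine (22 genes), the smallest p belonged to GCNT3 (-0.14), B3GNT5 (-0.17), B3GNT8 (0.12) and B4GAT1 (-0.15). The label need not describe each member, and GCNT3 and B3GNT5 are also on the mucin-type and glycolipid lists. B3GNT5 ran from -0.24 to -0.11 and B4GAT1 from -0.19 to -0.09 over single arrays left out, and the list had a camera adjusted p of 0.79. The sialylation list (28 genes, among them the sialidases NEU1, NEU2, NEU3 and NEU4, which remove sialic acid) had a camera adjusted p of 0.93. In it ST6GAL1, the main alpha2,6-sialyltransferase of N-glycans, was at -0.22 (SE 0.12), ST8SIA2 at 0.095, ST3GAL1 at -0.12 and ST6GALNAC4 at 0.23, whose other probe set was at 0.021. Leaving out 1 array in turn gave -0.29 to -0.08 for ST6GAL1, -0.19 to -0.04 for ST3GAL1, 0.06 to 0.14 for ST8SIA2 and 0.05 to 0.37 for ST6GALNAC4. The fucosylation list (16 genes, among them the fucosidase FUCA1) had a camera adjusted p of 0.59. Such mixed lists do not measure the direction of sialylation or fucosylation. GMDS, the first enzyme of GDP-fucose synthesis, had a log2 change of -0.17 (SE 0.06, limma adjusted p = 0.84), FUT4 was at -0.080, FUT1 at -0.10 and FUT3 at 0.089, with the other FUT3 probe set at -0.0088. Single arrays left out gave -0.15 to -0.02 for FUT1 and 0.03 to 0.14 for FUT3.

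**Figure D3:**
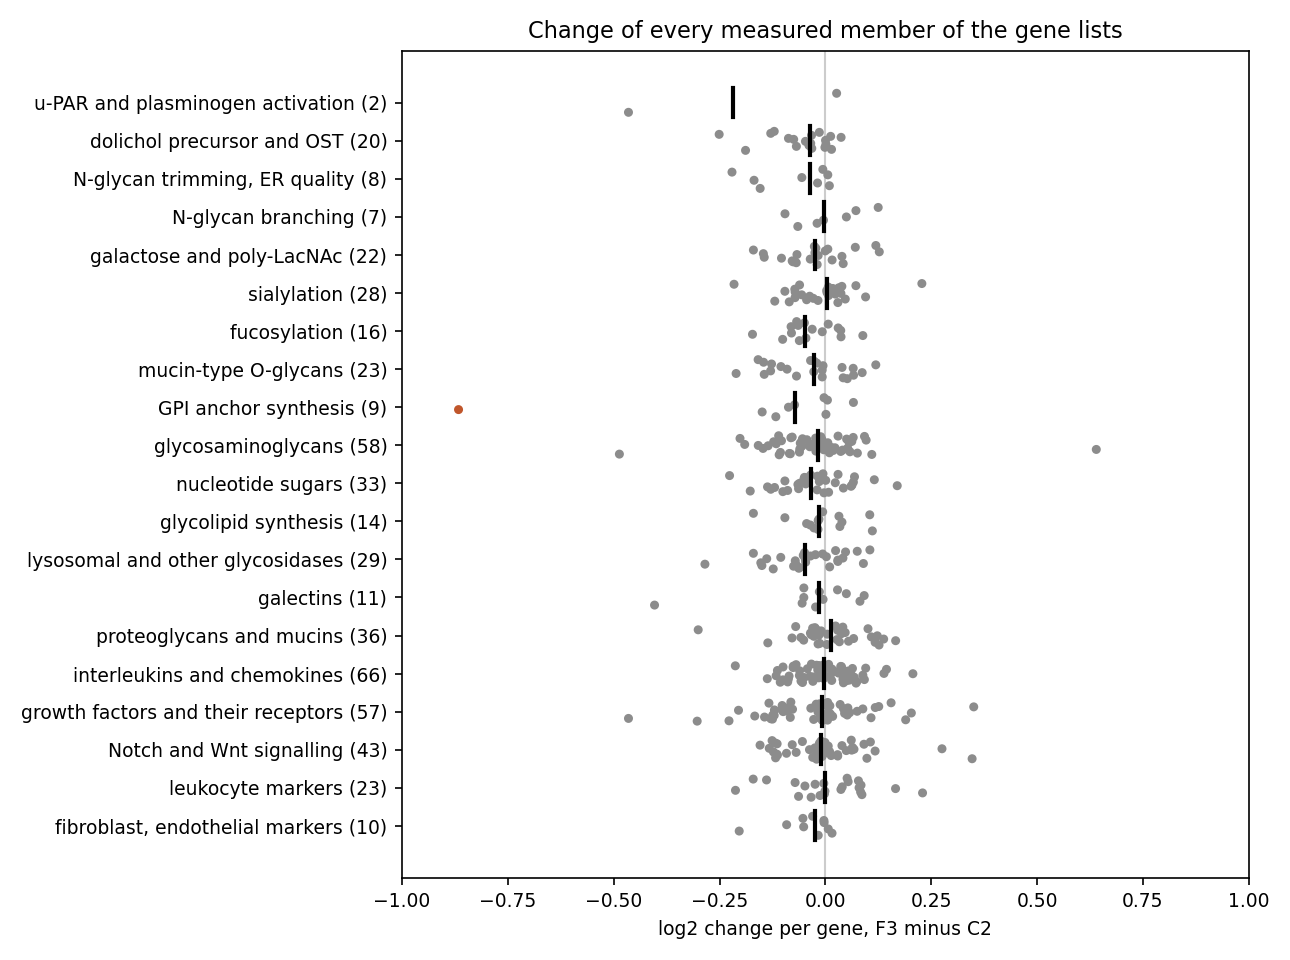
Log2 change (F3 minus C2) of every measured gene in 20 gene lists, with the number of genes in brackets, one point per gene, black bars at each list's median and orange for an adjusted p under 0.05. PIGB at -0.87 is the only orange point, and the list medians other than that of the 2-gene u-PAR list lie between -0.073 and 0.014.

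The remaining lists of glycan metabolism likewise held no member past the threshold over all probe sets. In glycosaminoglycan synthesis (58 genes, camera adjusted p = 0.75), PAPSS2 passed when adjusted over the list alone (limma adjusted p = 0.030), HAS2 did not, and B3GAT2 and CHST11 were at -0.20 and -0.12. Nucleotide sugar synthesis and transport (33 genes, adjusted p = 0.60) was led by the transporter SLC35B4 (-0.23), with UAP1 at 0.17 (0.11 to 0.23 over single arrays left out) and PMM1 at -0.14. Mucin-type O-glycan genes (23, adjusted p = 0.60) were led by GALNT15 (-0.15) and GCNT3, then GALNT7 (-0.13) and GALNT6 (-0.21), which ran from -0.17 to -0.07 and from -0.33 to -0.08 with 1 array left out in turn. GALNT15, B3GAT2 and CHST11 had low log2 levels in C2, of 3.12, 3.41 and 3.24. Glycolipid synthesis (14 genes, adjusted p = 0.79) was led by B3GNT5, B4GALNT1 (0.11), GBGT1 (0.10) and ST8SIA5 (-0.096); over single arrays left out GBGT1 ran from 0.07 to 0.15 and ST8SIA5 from -0.16 to 0.01. Lysosomal and other glycosidases (29 genes, adjusted p = 0.47) were led by GUSB (-0.15), with IDUA at 0.090 and IDS at -0.28 (-0.42 to -0.15 with 1 array left out in turn), whose other probe set was at -0.021. In the galectin list (11 genes, adjusted p = 0.84), LGALS3 passed when adjusted over the list alone (limma adjusted p = 0.0017), and LGALS9, LGALS2 and LGALS7 were at 0.082, 0.092 and -0.055, LGALS2 running from 0.04 to 0.16 and LGALS7 from -0.08 to -0.04 over single arrays left out. Among 36 proteoglycan and mucin genes (adjusted p = 0.35), BCAN passed over the list alone (limma adjusted p = 0.021), while MUC5B, NCAN and BGN were at 0.14, 0.12 and 0.12.

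In the list of u-PAR and plasminogen activation genes only 2 were measured, too few for a set test. IGF2R, at -0.46, passed when adjusted over these 2 genes (limma adjusted p = 0.0034) and not over all probe sets, and MRC2, the collagen receptor that associates with u-PAR, was at 0.027 (95% interval -0.16 to 0.22) and turned negative without F3 replicate 2 and without C2 replicate 2. In the 57 growth factor and receptor genes (camera adjusted p = 0.79), FGFR2 was at -0.30 and MET at -0.23, beside IGF2R and GDF15. Adjusted over this longer list alone, IGF2R did not pass (limma adjusted p = 0.097). Values adjusted over a list alone were not corrected across the lists. The 66 interleukin and chemokine genes had an adjusted p of 0.60, with CCR10 at -0.21, CCL4 at 0.21, CX3CR1 at -0.14 and CCL5 at 0.14. The 43 Notch and Wnt genes had an adjusted p of 0.79, with the Notch ligand JAG1 at 0.35 (SE 0.13) and the Notch target HES1 at 0.28 (SE 0.13), WNT5A at -0.11 and WNT3 at -0.12; none of the 4 passed. JAG1 differed by 0.60, -0.05 and 0.48 in the 3 pairs, and leaving out 1 array in turn gave 0.13 to 0.39 for HES1. Markers of other cell types held no member past the threshold in limma. The 23 leukocyte genes had a median change of -0.0010 (adjusted p = 0.57), with CD72, KLRC1 (-0.21), SIGLEC5 (0.17) and CLEC4D (-0.14) leading, and the 10 fibroblast and endothelial genes had a median of -0.023 (adjusted p = 0.60), with ICAM2 at -0.20, PDGFRB at -0.091, LUM at -0.051 and VCAM1 at -0.053. Single arrays left out gave -0.15 to -0.01 for PDGFRB, -0.10 to -0.0012 for LUM and -0.12 to -0.01 for VCAM1. Several of the genes named in these lists had low log2 levels in C2, such as KLRC1 (2.60), CLEC4D (2.83), LUM (2.32), VCAM1 (3.04), CX3CR1 (3.01) and WNT5A (3.12).

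Of 19 lists tested, 0 passed a camera adjusted p of 0.05, 2 had an unadjusted p under 0.05 (trimming and ER quality control at 0.036, and GPI anchor synthesis; 0.054 and 0.066 with the replicate block), and fry and camera with an estimated correlation also called 0. For 6 lists the median, the mean and the camera direction did not all have the same sign; they were branching, sialylation, glycolipids, interleukins and chemokines, Notch and Wnt, and leukocyte markers.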

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

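Leaving out both arrays of number 2 and leaving out probe sets ending in _x_at were chosen after the data were seen. The PIGB change kept its sign in all 14 alternatives with a limma fit, between -0.96 and -0.74, and its adjusted p, from 0.0045 to 0.15, passed in 10 of them. Leaving out 1 array in turn gave -0.96 to -0.78 and 0 to 2 probe sets past the threshold; without both arrays of number 2 the change was -0.74 and HAS2 was the 1 probe set past it. The replicate block gave 2 probe sets (PIGB and S100A10), an adjusted p under 0.10 gave 2 (PIGB and LGALS3) and the ordinary two-sample test gave 0, with 67 at an unadjusted p under 0.05; limma with the same arrays gave 1 and 68. The block changed no other call. The number of gene lists past the threshold was 0 with all arrays and 0 to 1 when single arrays were left out, the 1 being GPI anchor synthesis. With all arrays, that list's camera adjusted p was 0.91 with an estimated correlation and 0.60 without PIGB. Of the 79 genes that the rule names, 78 did not pass at an adjusted p under 0.05, and 2 of these did in some alternative, HAS2 and S100A10. Leaving out 1 array moved the change of 36 of these 78 by over 1.5 times, up or down, and did not move PIGB by as much. For 10 results close to 0, none past the threshold, the direction turned in some alternative, and the cause was not tested. With median centring MGAT2 was at 0.011. With quantile normalization MGAT1 was at 0.012 and MGAT2 at 0.062, and the mean shift of a list against other genes was 0.0019 for nucleotide sugars and -0.00063 for interleukins and chemokines. Without dim probe sets nucleotide sugars were at 0.0034. Without both arrays of number 2, MGAT1 was at 0.097, MGAT2 at 0.0050, MRC2 at -0.083, ST8SIA5 at 0.050, VCAM1 at 0.013, glycosaminoglycans at 0.024 and nucleotide sugars at 0.020. Leaving out single arrays gave -0.11 to 0.074 for MGAT1, -0.12 to 0.065 for MGAT2, -0.034 to 0.10 for MRC2 and -0.16 to 0.013 for ST8SIA5; for the lists it gave -0.034 to 0.0073 (galactosylation), -0.023 to 0.015 (glycosaminoglycans), -0.030 to 0.011 (nucleotide sugars) and -0.0098 to 0.014 (sialylation). Keeping control probe sets or those of other species in the test, and the alternatives for PLAUR, were not run, since none was set apart or analysed here. With 3 arrays per group the median 95% half-width of a change was 0.15 on the log2 scale.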

Other observations

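The tests on PIGB other than that on its chromosome neighbours, and the counts over other splits of the arrays, were chosen after the result was seen. The array carries 41 ribosomal protein genes among its housekeeping genes; their median log2 change was -0.0027 (0.013 after median centring), 0 passed in limma, and the 2 with an unadjusted p under 0.05 were both lower in F3. Some genes varied more between arrays of one population than between the populations. ALG11, a mannosyltransferase of the dolichol-linked precursor, ranged from 5.17 in C2 replicate 2 to 6.28 in C2 replicate 1, and PSENEN, a subunit of gamma-secretase, from 8.80 to 9.87 in the same 2 arrays. The glycosaminoglycan linker enzyme B3GAT3 was at 7.76 in C2 replicate 2 against 7.09 and 7.11 in the other C2 arrays. These genes were picked after their values were seen. C2 replicate 2 was the lowest or highest array in each of them, so the spread may belong to that array. It also had the highest PIGB value, 7.45. The array weights were 0.76 for C2 replicate 2 and for F3 replicate 1, and 1.47 for F3 replicate 2. With these weights the PIGB change was -0.88 (limma adjusted p = 0.011).

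Same-numbered arrays resembled each other. The probe set uc002gkc.1_a_at, unnamed here, had means of 7.49, 6.01 and 6.48 over both populations at numbers 1, 2 and 3, and was the 1 probe set for which the replicate number passed in limma (adjusted p = 0.018, with 166 probe sets at an unadjusted p under 0.05). B3GNT2, a poly-N-acetyllactosamine synthase, came next among named genes, at 6.46, 6.60 and 6.93 (adjusted p = 0.26), and did not pass.

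PIGB was lower in cells sorted for low surface u-PAR, which is GPI-anchored. A hypothesis not tested here is that the sort selected cells with a reduced step of anchor synthesis; surface staining of other GPI-anchored proteins in both populations would test it. A shift of whole arrays left in the deposited values would move most probe sets with PIGB, but the median change of all probe sets was -0.0064. RMA makes the array distributions alike, so a small median change was largely fixed in advance. It cannot decide on an error of the normalization limited to some probe sets. A fall of the whole pathway would bring the other GPI genes to changes close to that of PIGB. Among the measured ones with a mean above the median of all probe sets, however, the lowest 95% bound was -0.36, for PIGH. Only 9 of the list's 30 genes were measured, PIGB among them, so these values do not cover the rest of the pathway. Loss of a chromosome segment would lower the array genes that it reaches. Of the 3 nearest named ones on each side with a mean above the median of all probe sets (SRP14, CHST14, DLL4, APH1B, RPL4 and GLCE), the median change was -0.027. Their distance from PIGB is not given here, and a deletion that ends short of them, even a large one, remains possible. Whether the probes also read another transcript, such as CCPG1, cannot be told apart from a change of PIGB, because 0 other PIGB probe sets were in the table, and a difference between the populations that arose by drift during cloning or sorting was not tested.

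Of the 10 splits of the 6 arrays into 3 and 3, 2 gave at least the real count of 1 probe set past the threshold (highest other, 2), and 4 gave at least the real 68 with an unadjusted p under 0.05 (highest other, 138); 10 splits are too few for a share under 0.05. The split with 138 set C2 replicate 1, F3 replicate 1 and F3 replicate 2 against the rest. It is one of 6 splits that keep same-numbered arrays together at 2 of the 3 numbers, and the other 5 gave 22, 51, 64, 79 and 106. Among the 4 splits that part all 3 pairs as the real one does, the other 3 gave 0 probe sets past the threshold and 16, 25 and 32 at an unadjusted p under 0.05. The largest absolute log2 change of the real split, 0.87 for PIGB, was exceeded at 1.08 and 0.89 in splits that keep same-numbered arrays together at 2 numbers. In the other 3 splits that part all pairs it was 0.43, 0.50 and 0.32.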
